A study of Mus musculus with 10 samples.

How the data were processed

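Gene expression was measured in regulatory T (Treg) cells on 10 one-colour Affymetrix arrays. Per the labels, CD4+ YFP+ cells were sorted from spleen and pLN of mouse chimeras, and the arrays fall into 5 WT and 5 Fntb KO Treg samples. Per the labels' protocols, total RNA was isolated with a column kit and amplified and biotin-labelled with NuGEN kits. Per the submitters' processing notes, RMA in Affymetrix Expression Console 1.1 gave the values. RMA corrects the background, makes the arrays' distributions alike by quantile normalization and summarises the probes of each probe set. The values deposited by the authors are therefore on the log2 scale, where a difference of 1 is a 2-fold change. Further settings of that step are not given in the sources used here. The authors' table of the whole series and the series matrix held identical values (largest difference 0), and each column is 1 array.

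The files hold 41345 probe sets. GEO's platform annotation listed 25341 of them: 23521 with 1 gene symbol, which were used, and 1820 with several, which were left out. The other 16004 were unnamed here and were left out too. Symbols were looked up through Entrez identifiers in the RefSeq genes of assembly GRCm38.p6, in which 23328 of the 23521 probe sets matched, 193 did not, and 0 symbols had to be changed. Those genes served only for names and for which genes lie beside each other, because no genome build is named in the files. Of a gene with more than 1 probe set (1082 genes), the probe set with the highest mean over the 10 arrays was kept, which left 22180 genes. No filter on dim genes was applied.

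Fntb KO was compared with WT in limma 3.58.1 (R 4.3.3, with statmod 1.5.0 and version 1.17.8 of data.table), with lmFit and eBayes, no covariate, and a Benjamini-Hochberg adjusted p under 0.05 as the threshold. Every adjusted p given for a gene comes from this fit over all genes tested, unless another is named. A positive log2 difference means higher in Fntb KO. Errors are the SD over 5 arrays or the standard error (SE) of the difference. For Fntb and Foxp3 an exact two-sided permutation test over the 252 assignments of the arrays was added, whose smallest possible p is 0.00794.

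Lists of genes for T cell states, metabolism, signalling and prenylation, and marker lists of other cell types that a sort could hold, were fixed before the data were examined. So were the tests, the rule for named genes and most alternatives. Of the list members, 48 entries were not used, 30 because no probe set named them and 18 because their probe set named several genes. Each list was tested with limma's camera at its preset inter-gene correlation of 0.01, two-sided, which compares the list's genes with all others. Adjustment ran over the program lists together and over the marker lists together. Camera with a correlation estimated for each list, and fry, which asks whether a list's genes move one way on balance, were run as alternatives.

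The named genes are Fntb and Foxp3, and the 10 largest rises and 10 largest falls among genes past the threshold whose Fntb KO arrays all lay on one side of all WT arrays. Predicted or unnamed genes, small RNAs, receptor and immunoglobulin segments and sex-linked check genes were left out of those. Added to them are up to 4 members per program list with the largest change among those past the threshold, or the 2 with the largest change if none passed. From each marker list the member with the largest change is named. Genes named outside this rule are marked as chosen after their values were seen.

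The labels do not say that the samples of a group came from separate animals, so p-values measure only the spread between these samples, which may be technical. The replicate numbers are names only and pair nothing. The number of arrays limits the precision. On simulated data with 5 arrays per group and 22180 genes, the fit recovered 47.1% of genes changed by 0.5 on the log2 scale, 93.8% of those changed by 1 and 100% of those changed by 2. Of its 170 calls 10 were false. The simulated genes varied independently of each other, without the shared differences between arrays that the real data hold. These rates may therefore not hold for the real arrays. No detection calls were used. As a guide to the level of genes that T cells do not express, chosen after the data were seen, the 1105 olfactory receptor genes had a median log2 value of 2.51 and a 95th percentile of 4.19. Folds of genes near that level can understate the true change.

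Alternatives were another quantile normalization of the gene values, only genes at or above the median level, eBayes with trend and robust, array weights, the mean of a gene's probe sets, the authors' own table, a minimum log2 change of 0.5, a test of every probe set, and leaving out each array in turn. A block for the 3 arrays with the lowest medians, and a fit without them, were chosen after seeing the data.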

Results

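The data describe Treg cells that express the protein farnesyltransferase subunit Fntb and Treg cells in which a Foxp3-driven Cre removes it. Fntb encodes the beta subunit of the enzyme that attaches a farnesyl lipid to proteins, and Foxp3 is the lineage transcription factor of Treg cells. The design asks which transcripts of sorted Treg cells depend on Fntb, and the study's title places the question in effector Treg cells. There were 5 WT and 5 Fntb KO arrays. Array medians ran from 4.09 to 4.25 on the log2 scale, and arrays of 1 group correlated at 0.985 to 0.995. WT 2, Fntb KO 1 and Fntb KO 2 had the lowest medians (4.10, 4.12 and 4.09). They also had the highest medians of mitochondrial ribosomal protein genes, up to 7.11, all above the 6.35 to 6.69 of the other arrays. They stood apart on the first principal component, which held 24.7% of the variance, while the second (20.2%) separated the genotypes.

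The targeted transcript was lower in every Fntb KO array. Fntb was 6.12 ± 0.16 in WT and 5.47 ± 0.12 in Fntb KO (log2, SD, n = 5 each), a difference of -0.65 (SE 0.0963) or 1.57-fold, with an adjusted p of 0.00442 and an exact two-sided permutation p of 0.00794, the smallest that 5 against 5 arrays allow. The probe set may cover exons outside the deleted part, and its position against the deletion was not examined. Foxp3 was 10.67 ± 0.03 in WT and 10.53 ± 0.05 in Fntb KO, a difference of -0.14. Its 2 groups did not overlap (exact permutation p = 0.00794), but its adjusted p of 0.601 over all genes did not pass the threshold.

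Loss of Fntb was accompanied by more decreases than increases. Of 22180 genes, 179 fell and 67 rose, and 48 of the lowered and 11 of the raised genes changed at least 2-fold. Among genes that the naming rule admits, the largest fall was in Tigit, an inhibitory receptor of T and NK cells, which went from 6.99 ± 0.63 to 3.55 ± 0.25 (SD, n = 5 each), 10.9-fold lower with an adjusted p of 1.97e-05. The other largest falls were in Khdc1a (5.52-fold), the chemokine receptor Ccr4 (4.85-fold), the calcium-binding proteins S100a4 (4.74-fold) and S100a6 (4.58-fold), the phosphatase-family gene Mtmr9 (4.34-fold), the cytokine Il10 (4.28-fold), the linker histone H1f5 (4.25-fold), the transcription factor Maf (4.17-fold) and the decoy interleukin-1 receptor Il1r2 (4.10-fold). The predicted gene Gm6637, which the rule leaves out and which is named after its value was seen, had a larger difference of -3.57. In Fntb KO, Tigit, Ccr4, Il10, H1f5 and Il1r2 lay below the 95th percentile of olfactory receptor genes (4.19).

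Under the same rule the largest rises were in Sycp1, a component of the meiotic synaptonemal complex, at 4.35-fold, and in the interferon-inducible family gene Ifi213 at 4.04-fold. They were followed by the F-box gene Fbxo17 (2.72-fold), the olfactory receptors Olfr372 (2.20-fold) and Olfr373 (2.18-fold), Lrrc23 (2.14-fold), Zfp868 (2.11-fold), Tmie (2.07-fold), Als2cl (2.03-fold) and Erp27 (1.89-fold). Sycp1, Olfr373 and Lrrc23 lay below 4.19 in WT, and Olfr372 in both groups. Fbxo17 went from 6.14 ± 0.16 to 7.58 ± 0.25 (SD, n = 5 each), with an adjusted p of 6.27e-05. In all, 592 genes (2.67%) had groups that did not overlap, where chance gives 0.794%. The call count depended on the arrays. With the 3 low-median arrays as a block 275 genes were lowered, and 245 of the 246 calls were shared, while without those arrays 41 were raised and 109 lowered; both fits were chosen after seeing the data. There were 32, 33 and 35 raised and 95, 102 and 118 lowered without WT 3, WT 4 and WT 5. Without WT 2, 116 genes were lowered, and without WT 1, 192. Erp27 and Khdc1a did not pass without the 3 low-median arrays (adjusted p 0.0603 and 0.0565), at differences of 0.89 and -2.42, and Olfr372 lost its call without 4 of the 10 arrays in turn, at differences of 1.02 to 1.11.

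**Figure D1:**
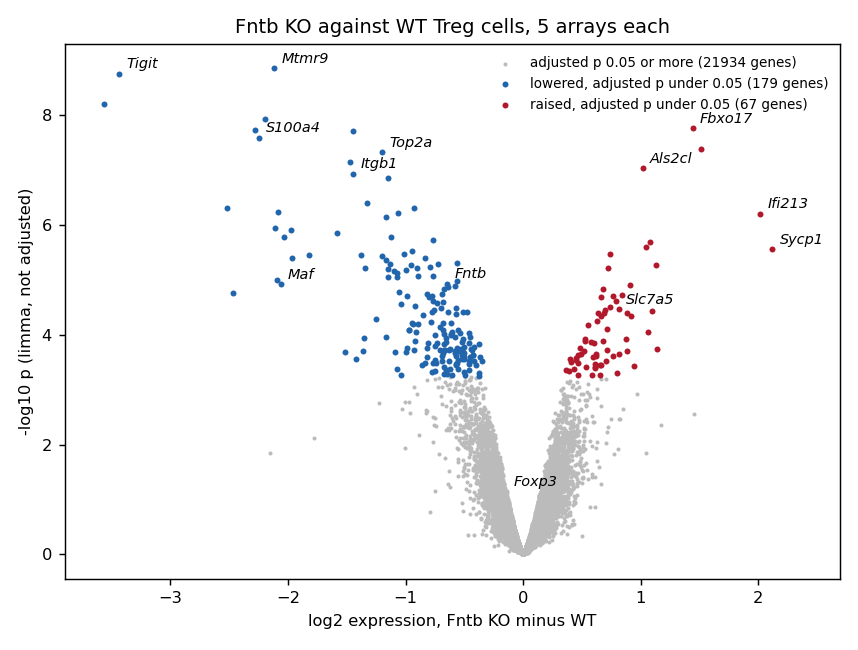
Each point is 1 of 22180 genes, with the log2 difference (Fntb KO minus WT) on the x axis and -log10 of limma's unadjusted p on the y axis; blue marks the 179 lowered and red the 67 raised genes at an adjusted p under 0.05. Tigit and Mtmr9 stand at the upper left, and Foxp3 lies among the genes that did not pass.

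Effector Treg genes fell together. Of 28 measured members, 16 fell and 0 rose, and the list's median difference was -0.82. Beside Tigit, Ccr4, S100a4, S100a6, Il10 and Maf, the lowered members were the integrin Itgae (-1.47), the chemokine receptors Ccr2 (-1.42) and Cxcr3 (-1.15), the transcription factors Irf4 (-0.95), Batf (-0.65) and Prdm1 (-0.55), and Klrg1 (-0.94), Lag3 (-0.82), Icos (-0.77) and Cd44 (-0.69), which complete the 16 and were named after their values were seen. Id2 (0.16) and Myb (0.24) were the only measured members with a positive difference, and neither passed over all genes. Adjusted over the list alone, 24 members were lower and 1 higher. Camera gave an adjusted p of 4.94e-42, and the call held with an estimated correlation (adjusted p = 0.00464). Without the 3 low-median arrays the list's median was -0.79.

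Proliferation genes were also lower. All 30 measured cell cycle genes had a negative difference, with a median of -0.27, and 3 of them fell while 0 rose. Top2a, the topoisomerase of dividing cells, went from 5.61 ± 0.18 to 4.42 ± 0.17 (SD, n = 5 each), 2.29-fold lower with an adjusted p of 0.000106, and the proliferation marker Mki67 fell 1.90-fold. The mitotic checkpoint kinase Bub1b fell 1.33-fold, lay below 4.19 in both groups, and lost its call without the 3 low-median arrays (adjusted p = 0.140) and without 9 of the 10 arrays in turn. Its difference was -0.42 with all arrays, -0.43 without those 3 and between -0.47 and -0.37 without each array. There were 12 lower members adjusted over the list alone. The list's adjusted p was 1.08e-16, and 0.00464 with an estimated correlation.

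Homing receptors and integrins fell as a list of 17, with 5 lowered members, 0 raised and a median of -0.24. The integrin chain Itgb1 went from 8.84 ± 0.31 to 7.39 ± 0.20 (SD, n = 5 each), 2.73-fold lower with an adjusted p of 0.000200. Itgb8, whose integrin activates latent TGF-beta, fell 2.24-fold, the chemokine receptor Ccr6 fell 2.02-fold, and the gut-homing receptor Gpr15 fell 1.53-fold from a level below 4.19 in both groups. Adjusted over the list alone, 7 members were lower and 1 higher. The list's adjusted p was 1.03e-09, and 0.00915 with an estimated correlation. Without the 3 low-median arrays 3 members were lowered and 1, Ccr9, was raised (0.66, adjusted p 0.0386), and the list's median was -0.21. Gpr15 did not pass there (adjusted p = 0.0579), at a difference of -0.64 against -0.62 with all arrays.

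**Figure D2:**
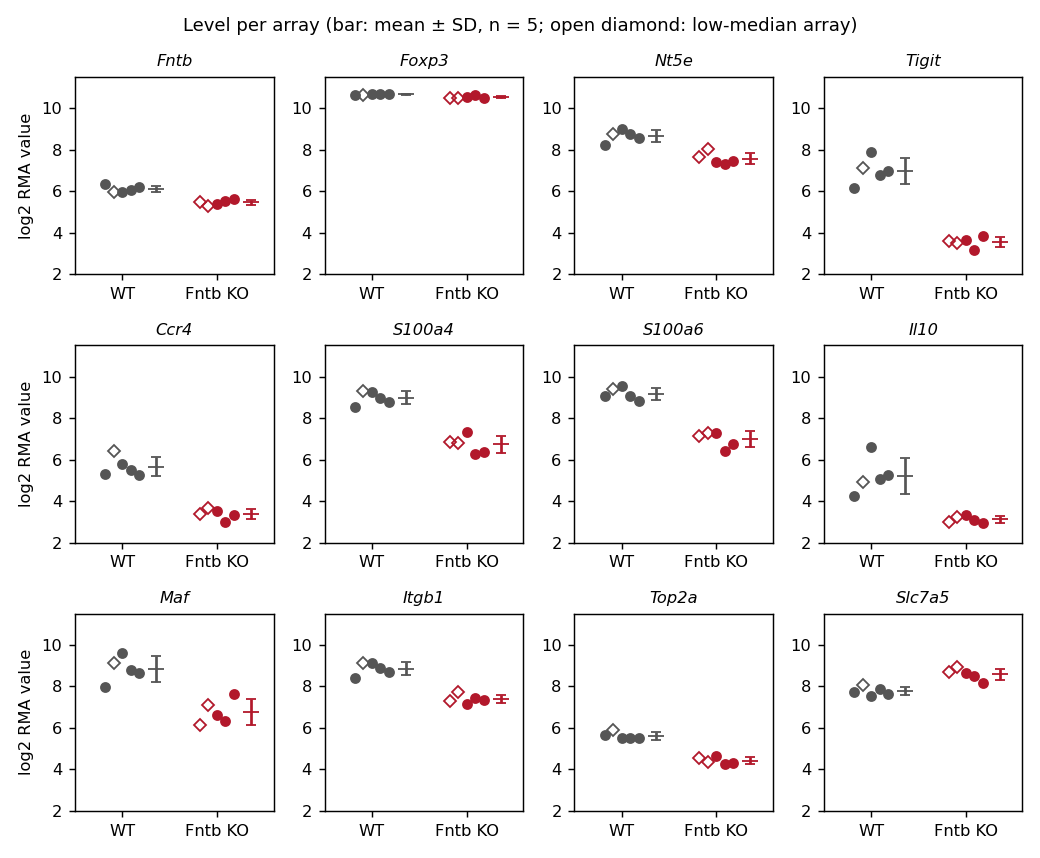
The log2 RMA value (y axis) of 12 genes is shown for each of 5 WT and 5 Fntb KO arrays, with bars for the mean ± SD and open diamonds for the 3 low-median arrays. Tigit, Ccr4, S100a4, S100a6, Il10, Maf, Itgb1, Top2a and Nt5e are lower in every Fntb KO array than in any WT array, and Slc7a5 is higher in every one.

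Treg identity genes were lower as a list at camera's preset correlation (median -0.27, adjusted p 5.36e-07), a call that was lost at adjusted p = 0.0861 with an estimated correlation. Of 19 measured members, 3 fell and 0 rose: Nt5e, which makes extracellular adenosine (2.14-fold), the semaphorin receptor Nrp1 (1.87-fold) and Entpd1, which degrades extracellular ATP (1.47-fold). Il2ra differed by 0.05 and Foxp3 by -0.14, and neither passed; Il2ra is named after its value was seen. Adjusted over the list alone, 10 were lower, among them Ctla4 (-0.39) and Ikzf2 (-0.41), and 2 higher, Gpr83 (0.40) and Ecm1 (0.22). These members are named after their values were seen, and none of them passed over all genes. Entpd1 lost its call without the 3 low-median arrays (-0.43, adjusted p = 0.147) and without 5 of the 10 arrays in turn, where its difference ran from -0.57 to -0.51.

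Of the 16 measured helper T cytokines and lineage regulators, 2 fell and 0 rose. The median level of these members was 3.55 in WT and 3.71 in Fntb KO, below 4.19. Little therefore follows about the members near or below that level. Ifng, the Th1 cytokine, fell 2.22-fold to a level below 4.19, and Cxcr5, which guides cells to B cell follicles, fell 2.11-fold. The list's median was -0.10 and its adjusted p 0.0126, with an adjusted p = 0.0833 with an estimated correlation. There were 3 lower members adjusted over the list alone. Of 19 resting or central T cell genes 1 rose, Als2cl, and 0 fell. Als2cl lies beside Tmie, which also rose. That list had a median of 0.15 and an adjusted p of 0.00290, and an adjusted p = 0.167 with an estimated correlation. Adjusted over the list alone, 2 were higher and 1 lower.

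Amino acid uptake and ATF4 target genes gave changes in both directions. Of 19 measured members 2 rose and 1 fell. The amino acid transporter Slc7a5 went from 7.77 ± 0.20 to 8.59 ± 0.27 (SD, n = 5 each), 1.76-fold higher with an adjusted p of 0.00897. The stress-induced transcription factor Ddit3 rose by 0.59 on the log2 scale, and lost its call without 9 of the 10 arrays in turn, at differences of 0.51 to 0.63. The glutamine transporter Slc1a5 fell 1.46-fold, and lost its call without WT 3 (adjusted p = 0.0521) at a difference of -0.55, as with all arrays. The list's median was 0.10 and its adjusted p 0.0273, with an adjusted p = 0.167 with an estimated correlation. With 4 higher and 1 lower, 5 members passed adjusted over the list alone. Without the 3 low-median arrays the list did not pass (adjusted p = 0.0655), at a median of 0.10.

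In 5 further lists that passed camera's test, no member passed over all genes in the fit described. Glycolysis genes had a median of -0.13 over 17 members (adjusted p 0.00183, but adjusted p = 0.167 with an estimated correlation), with Pgam1 at -0.34 and Tpi1 at -0.34, and 0 members passed over all genes or adjusted over the list alone. Unfolded protein response genes had a median of -0.16 over 15 members (adjusted p 4.07e-05, but adjusted p = 0.167 with an estimated correlation), with Calr at -0.38 and Pdia6 at -0.35, and again 0 members passed adjusted over the list alone. Immediate early and TCR-induced genes had a median of -0.10 over 24 members (adjusted p 0.0109, but adjusted p = 0.167 with an estimated correlation), with Nr4a2 and Egr2 at -0.48 each and 0 members adjusted over the list alone. RAS-ERK feedback genes had a median of -0.11 over 12 members (adjusted p 0.0192, but adjusted p = 0.167 with an estimated correlation), with Dusp4 at -0.71 and Spry1 at -0.33, and 2 lower and 1 higher adjusted over the list alone. Neither of these 2 lists passed without the 3 low-median arrays (adjusted p 0.0649 and 0.0518), though their medians there, -0.12 and -0.15, were not smaller in size. Interferon-stimulated genes had a median of 0.12 over 14 members (adjusted p 0.0247), with Ifit1 at 0.66 and Oasl2 at 0.51 and 1 member higher adjusted over the list alone. This list too had an adjusted p = 0.167 with an estimated correlation. Ifit1 (adjusted p 0.0559) and Dusp4 (0.0550) lay close to the threshold, and both passed among genes at or above the median level (0.0456 and 0.0455) and with array weights (0.0319 and 0.0286).

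Of the prenylation enzymes only Fntb passed in the fit described. The list of 14 had a median of -0.05 and an adjusted p of 0.128 (0.518 with an estimated correlation). Fntb was its 1 lower member, also adjusted over the list alone. Because the list includes the deleted gene itself, part of any shift in it follows from the knockout. Without the 3 low-median arrays the list had a median of -0.13 and, at the preset correlation, an adjusted p of 0.00453. Chml, named after its value was seen, was lower there as well (-0.57, adjusted p 0.0421). Sterol synthesis and uptake genes had a median of -0.02 over 18 members (adjusted p 0.855), with Tm7sf2 and Stard4 at 0.39 each and 1 higher adjusted over the list alone. Farnesylated CaaX proteins, the substrates of the enzyme, had a median of 0.04 over 16 members, a mean and a camera direction below 0 and an adjusted p of 0.855. Cenpf was at -0.34 and Lmnb2 at 0.32, both below a level of 4.19 in both groups, and 1 member was lower adjusted over the list alone. Oxidative phosphorylation genes had a median of -0.06 over 21 members (adjusted p 0.0819, and 0.668 with an estimated correlation). Atp5a1 was at -0.26 and Cox5a at -0.19, and without the 3 low-median arrays the preset correlation gave an adjusted p of 0.00226. Apoptosis and p53 target genes had a median of -0.05 over 19 members (adjusted p 0.158), with Pmaip1 at -0.44 and Bcl2l11 at 0.38. In the last 2 lists 0 members passed adjusted over the list alone.

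**Figure D3:**
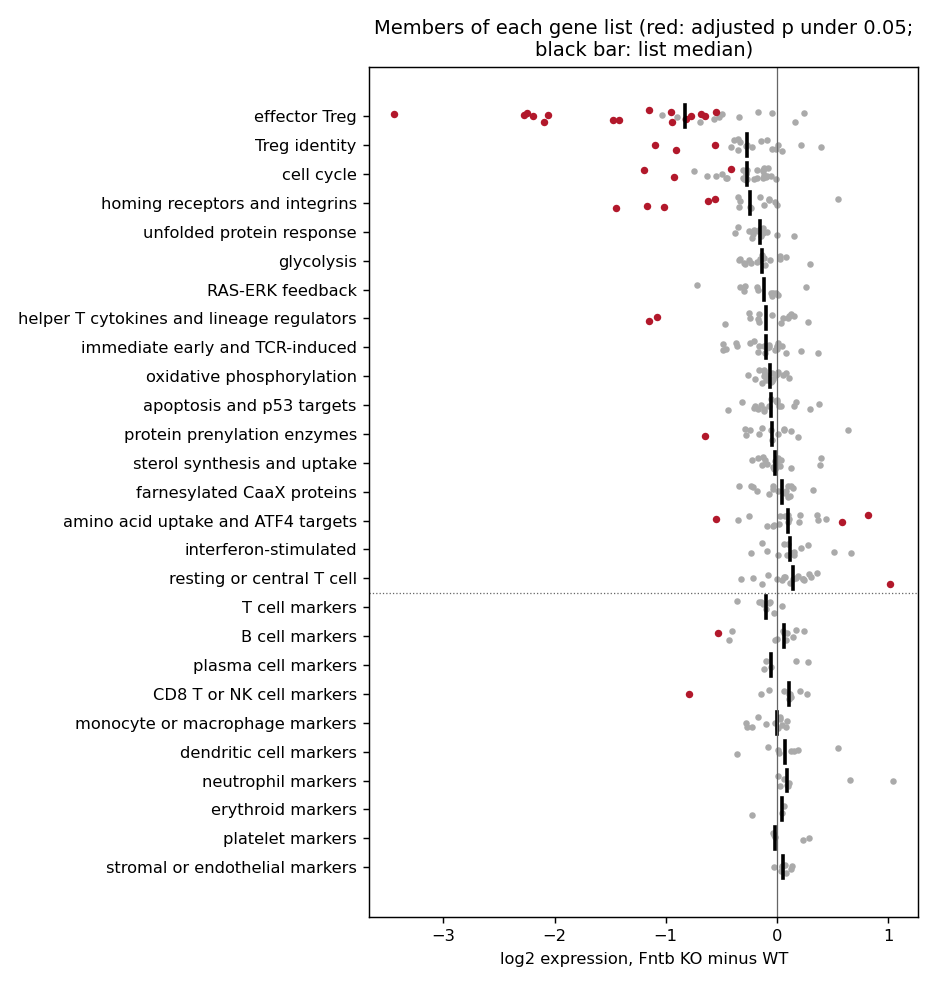
Each point is the log2 difference (Fntb KO minus WT, x axis) of 1 member of a gene list (y axis), red where the adjusted p over all genes was under 0.05, with a black bar at the list's median and the marker lists under the dotted line. The effector Treg list has the lowest median, -0.82, and 16 red points.

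Markers of other cell types were followed because the sort gate could hold other cells. No marker list passed camera's test in the fit described. T cell markers had a median of -0.10 over 9 genes (adjusted p 0.142), at levels of 10.79 in WT and 10.67 in Fntb KO. They passed with the 3 low-median arrays as a block (adjusted p 0.0215, median -0.12) and with trend and robust (0.0475). Without Fntb KO 2, T cell and neutrophil markers passed (0.0166 each). The adjusted p was 0.640 for B cell, plasma cell and erythroid markers, 0.716 for CD8 T or NK cell markers, 0.391 for monocyte or macrophage markers, 0.155 for neutrophil markers, and 0.392 for dendritic cell, platelet and stromal or endothelial markers. Of single markers, the immunoglobulin heavy chain Ighm fell 1.45-fold and the cytotoxic granule gene Nkg7 fell 1.73-fold. Ighm lost its call without 6 of the 10 arrays in turn, and Nkg7 without the 3 low-median arrays (adjusted p = 0.0750). The difference of Ighm in those fits ran from -0.55 to -0.48 against -0.53 with all arrays, and that of Nkg7 was -0.74 against -0.79. Immunoglobulin genes share sequence, so the size of the fall is uncertain: another probe set of Ighm differed by -1.81, and a probe set that names several immunoglobulin genes by -2.50 (adjusted p 0.00820). The markers with the largest difference in the other lists did not pass: Derl3 (0.28), Csf1r (-0.28), Ccr9 (0.55), S100a8 (1.05), Car1 (-0.23), Pf4 (0.29) and Pecam1 (0.13). S100a8 was 4.80 ± 1.03 in Fntb KO and 3.75 ± 0.25 in WT (SD, n = 5 each).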

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

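The test of lists with an estimated correlation under other splits was chosen after the results were seen. So were both tests of other cells diluting the Treg cells and the fit without the 3 low-median arrays. The bound for that fit and the other tests here were set down before. The effector Treg genes were lower in Fntb KO. Cells other than T cells that passed the CD4+ YFP+ sort could dilute every T cell transcript alike. However, the T cell markers' median lay 0.73 above the effector list's (95% bootstrap interval over genes 0.51 to 1.00). Bootstrap intervals over genes treat the genes as independent and carry no spread between arrays. CD4 T cells that lack Foxp3 would keep the T cell markers but dilute Foxp3 with the effector genes. Foxp3 differed by -0.14 (95% interval from the fit over arrays -0.29 to 0.01), where the effector median's bootstrap interval over genes was -1.09 to -0.62. The 3 low-median arrays were not the source either, since the effector median was -0.79 without them. Neither dilution test can see a smaller share of effector cells among the sorted Treg cells, which would leave T cell markers and Foxp3 unchanged. Arrays of whole samples cannot tell such a shift from lower expression per cell, so that question is left open.

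Chance is an unlikely source of the number of genes. Of 100 splits of the arrays into 5 and 5, only the real one gave as many as 246, and the highest other gave 2. This concerns chance between these samples and not between animals, which the labels do not tell apart. For program lists at the preset correlation, 2 of 100 splits gave as many as the real 12, and the highest other gave 12 as well, with WT 1 and Fntb KO 1, 2, 3 and 4 on one side. That split exchanges 1 array of each group with the real one and so still carries most of the genotype contrast, as do the 19 drawn splits of that kind, which gave a median of 8 lists. The 80 splits that exchange 2 arrays of each group carry less of it, and gave a median of 2 lists and at most 9. With no genotype effect all splits would be alike, so the place of the real split among them is a test, but where there is one the other splits' own counts, those of genes included, are not what unchanged groups would give. With an estimated correlation only the real split gave its 3 lists (1 of 100), and the highest other gave 0. For marker lists the real count was 0, so all 100 splits gave as many by construction and nothing follows about chance; the highest other gave 3.

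Of 184 groups tested for an array far from the rest of its group, 13 stood out, where chance gives about 1 in 20 (9.20). Several are low-median arrays. In WT 2 the array median was 4.10, where the other WT arrays began at 4.19, and the list means were 6.76 for sterol synthesis and uptake, 5.39 for cell cycle and 8.52 for oxidative phosphorylation, above the other WT arrays. Ccr6 in WT 2 was at 6.46, where the others reached 6.01. In Fntb KO 1 the cell cycle mean was 5.12, above the other Fntb KO arrays, while Entpd1 at 5.75 and Itgb8 at 6.16 were below them. In Fntb KO 2 the mean of the resting or central T cell list was 8.45, above the others. Fntb KO 5 had Pgam1 at 5.99, below the others, and WT 1 had Pf4 at 2.58, below the others. WT 5 had a monocyte or macrophage mean of 5.52, below the others, and a neutrophil mean of 3.33, above them.

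Probe sets outside the comparisons also differed. Of the 1820 that name several genes, 7 passed an adjusted p under 0.05 in limma, 4 higher and 3 lower. Of the 16004 unnamed here, 37 passed, 10 higher and 27 lower.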

How the results depend on the processing

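The fits with a block for the 3 low-median arrays or without them were chosen after seeing the data. No paired analysis was possible because the labels number no replicates, and the numbers used here only name arrays. Fntb kept its direction and its call under every alternative run. The authors' own table is identical, so it tests nothing. The lists for effector Treg, cell cycle and homing kept their direction and call under every alternative run. The number of arrays and signal near the level of olfactory receptor genes limit what can be called. The causes of the changes below were not tested.

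With an estimated correlation, the adjusted p was 0.0861 for Treg identity, 0.0833 for helper T genes, and 0.167 each for resting, amino acid, glycolysis, interferon, immediate early, RAS-ERK and unfolded protein response genes. With fry it was 0.0511 for resting, 0.102 for amino acid and for glycolysis, 0.0853 for interferon, 0.143 for immediate early, 0.134 for RAS-ERK and 0.0710 for unfolded protein response genes. Among genes at or above the median level, immediate early and RAS-ERK genes gave 0.0595 each. Uncalled directions turned there for sterol (0.803), farnesylated (0.683) and CD8 T or NK cell genes (0.621), and with another quantile normalization for sterol (0.986) and farnesylated genes (0.835). With trend and robust, T cell markers gave 0.0475.

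With the 3 arrays as a block, 275 genes were lowered, and the adjusted p was 0.0124 for prenylation, 0.0598 for amino acid, 0.000236 for oxidative phosphorylation, 0.0555 for immediate early genes and 0.0215 for T cell markers. Without the 3 arrays, 41 genes were raised and 109 lowered, and 107 of the 246 calls were shared. The adjusted p was then 0.00453 for prenylation, 0.0655 for amino acid, 0.00226 for oxidative phosphorylation, 0.0649 for immediate early and 0.0518 for RAS-ERK genes, and uncalled directions turned for farnesylated genes (0.933) and B cell markers (0.882). The arrays with low medians hold 1 WT array, too few for a fit of their own. Of the 63 named genes, Erp27, Khdc1a, Entpd1, Bub1b, Gpr15 and Nkg7 lost and Egr2 and Ccr9 gained a call without the 3 arrays. Ifit1 gained a call with another quantile normalization (adjusted p 0.0203), Ifit1 and Egr2 with the block (0.0147 and 0.00947), Dusp4 with trend and robust (0.0448), Ifit1 and Dusp4 among genes at or above the median level, and Ifit1, Dusp4 and Ccr9 with array weights.

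Leaving out each array in turn gave 32 to 61 raised genes and 95 to 192 lowered, lowest without WT 3 and highest without WT 1. Raised genes were 33 without WT 4 and 35 without WT 5, and lowered genes 102, 118 and 116 without WT 4, WT 5 and WT 2. The adjusted p ranged from 0.0211 to 0.626 for prenylation, 0.212 to 0.998 for sterol, 0.00880 to 0.0932 for amino acid, 0.00345 to 0.858 for oxidative phosphorylation, 0.0103 to 0.109 for interferon, 0.00429 to 0.0864 for RAS-ERK and 0.443 to 0.973 for farnesylated genes. It ranged from 0.0166 to 0.428 for T cell, 0.0166 to 0.433 for neutrophil and 0.460 to 0.935 for B cell markers. The amino acid list lost its call without WT 1 (0.0921), Fntb KO 1 (0.0523) or Fntb KO 2 (0.0932), the interferon list without Fntb KO 1 (0.109) or Fntb KO 3 (0.101), and the RAS-ERK list without WT 3 (0.0864). Oxidative phosphorylation genes passed without WT 1 (0.0348), WT 3 (0.0374), WT 5 (0.0353), Fntb KO 1 (0.0188) or Fntb KO 2 (0.00345). Prenylation genes, a list that includes Fntb itself, passed without Fntb KO 1 (0.0297) or Fntb KO 2 (0.0211). T cell and neutrophil markers passed without Fntb KO 2 (0.0166 each).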

Other observations

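The families by symbol stem and the placement of changed genes by chance were chosen after the results were seen. So were the test of clustered against other changed genes and Fisher's exact test. No prediction was written for the count by chromosome, and the other tests here were set down before. Genes named below that the report does not name were chosen after their values were seen. Of 627 families of genes that share a symbol stem, 8 passed in camera at the preset correlation and 0 with an estimated correlation. The small nucleolar RNA host genes (Snhg) were higher in 14 of 15 members, with a median of 0.23, an adjusted p of 0.000224 and an adjusted p = 0.994 with an estimated correlation, and 0 single members passed. The other 7 were lower. The T cell receptor segments Trav had a median of -0.35 over 5 genes, 3 of them lowered (adjusted p 0.000687), and the Cxcr receptors -0.35 over 6 genes, 2 of them lowered (adjusted p 0.00236), each with an adjusted p = 0.627 with an estimated correlation. The Ccr receptors had a median of -0.29 over 10 genes, 3 of them lowered (adjusted p 0.00913), and the stem Mcm, whose genes mostly serve DNA replication, -0.12 over 10 genes (adjusted p 0.0417). Myo had a median of -0.08 (adjusted p 0.0203), Kif -0.05 (0.0245) and Vps -0.10 (0.0453). These 5 had an adjusted p = 0.994 with an estimated correlation. The lowered Cxcr and Ccr genes and several Mcm genes are also members of the program lists above. Those families are therefore not results separate from the lists. Without the 3 low-median arrays 9 families passed at the preset correlation, 5 of the 8 among them: Ccr (0.0754), Myo (0.0791) and Kif (0.0526) did not, while others, such as Psmd (0.00109), Snord (0.00147) and Ptpn (0.0243), did.

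Some genes of charged transfer RNA synthesis were higher. The synthetases Cars and Mars1 rose by 0.72 and 0.55 on the log2 scale (adjusted p 0.00280 and 0.0135). The hypothesis of a shared rise of the cytosolic synthetases, tested on the 15 not seen before, gave a camera p of 0.0964, with 9 higher and a median of 0.01, so no shared rise was found.

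In the RefSeq gene order of GRCm38.p6, 49 of the 246 changed genes had another of a different symbol stem among the 5 tested genes on either side. For 10000 random sets matched on level the median was 28 and the 95th percentile 40 (permutation p = 0.00220), so random placement is unlikely. Only symbol stems told neighbours apart, so a predicted transcript close to a named gene, such as Gm6637 close to Klrg1, counted as a neighbour. Whether such pairs share a transcript, and whether neighbours share regulation, was not tested. DNA of another mouse strain carried along with the Fntb allele may be a source: 3 of the 100 tested genes nearest to Fntb passed (Dhrs7, Hif1a and Snapc1), where random sets gave a median of 1 and a 95th percentile of 3 (permutation p = 0.100). The 49 may instead follow the effector state, but their median absolute within-group correlation with the effector list's mean was 0.238, where random sets had a median of 0.30 and a 5th percentile of 0.231, and the other 182 changed genes outside that list had 0.403 (permutation p of the difference 0.0540). Both values met the bounds set beforehand against these sources (3 or fewer genes, and a correlation at or under the random median), but not by more than the spread of the random sets, a condition added after the values were seen. Both sources are therefore left open, as is strain DNA elsewhere, which was not tested directly. In a count by chromosome against the random sets, no chromosome passed (lowest permutation adjusted p 0.137). A whole chromosome is too coarse a unit to show a short stretch.

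The 21 clusters held Mtmr9 with Xkr6, Tmie with Als2cl, Olfr372 and Olfr373 with Cyp4f18, and Nrp1 with Itgb1. Of the 10 largest rises named 4 were in clusters, and of the 10 largest falls named Khdc1a, Mtmr9 and Il1r2. Raised genes were in clusters in 25.4% and lowered genes in 17.9% of cases (Fisher's exact test, two-sided, p = 0.211).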
